A study of Sus scrofa with 10 samples.

How the data were processed

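The series holds RNA from 10 pig morula samples, 5 per group, prepared as fragmented cDNA libraries and sequenced in pairs on an Illumina instrument, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The deposited tables spell the DDB1_KD columns DBB1, and each was matched to its sample by group word and number. Tools named in the submitters' processing notes, without version, order or role, are fastp, HISAT2, HOMER, ChIPseeker, StringTie and edgeR, and the genome build named there is susScr11. Which of them made which value is not given in the sources used here.

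The deposited tables list 24358 genes and 47421 isoforms with FPKM values and estimated counts for each library, per the file headers. The deposited estimated counts are whole numbers, and in every library isoform counts equalled the deposited FPKM times isoform length times 1 constant. This held for 100% of counts above 0 within 1.5 counts plus 0.5%. Gene counts were the sums of isoform counts for all 24358 genes. FPKM computed from read tallies would show the same relations, so they cannot tell tallies of reads from estimates derived from coverage. The sampling error of these counts may thus not be that of read counts. Intervals and limits from counts cover counting error only. The deposited FPKM is 0.0001 wherever the count is 0. Whether counting used strand is not given in the sources used here. Of 94 genes named under the rule below, 34 overlap a gene on the other strand, and reads of such partners cannot be told apart. Symbols came from the table for 17451 genes, from a table of Ensembl names for 951 and from NCBI RefSeq gene names (Sscrofa11.1) for 719, and 5237 genes kept their identifier.

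The test written first was limma on log2(FPKM + 1), with edgeR to replace it if counts were present. Because the tables hold counts, the results reported are from edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling), run in R 4.3.3 on the estimated counts as deposited, which are already whole. Genes or isoforms with a mean FPKM of at least 1 over the 10 libraries were tested, 8476 genes and 11250 isoforms. The model had the group alone, and an adjusted p (Benjamini-Hochberg) under 0.05 counted as passed. Fold changes are DDB1_KD against NC with a prior count shrinking them slightly, and the SE is the unshrunken coefficient divided by the root of the F statistic. limma 3.58.1 (lmFit, eBayes with a trend, pseudocount 1) and DESeq2 1.42.0 were run beside it. Levels are FPKM as deposited, as mean ± SD. Log2 CPM values are TMM-scaled with a prior count of 2. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.

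The samples, the alternatives, the test and 30 gene lists were chosen before the data were examined. The lists came from textbook knowledge and none was chosen on these samples. The 27 with at least 5 tested genes entered limma's camera with a preset correlation of 0.01 between genes, and beside it camera with a correlation estimated per list, fry, which tests whether a list's genes move on balance one way, and an exact permutation of the list's mean over 252 assignments. DDB1 was left out of the CUL4 ligase list. Named are DDB1, the 5 genes per direction with the smallest p where no gene passes, a set of lineage and apoptosis genes whatever their p, and up to 4 members with the smallest p of each list described. RARS2 fell outside this rule for genes and was named after its values were seen, because it was the isoform that passed. Some genes of this set and 1 of the lists are not reported here.

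Library depth was 32466912 to 50911295 estimated counts. The edgeR fits and camera with the preset correlation were tested on simulated data drawn from these libraries' means and spread, with 200 changed genes. The other tests reported here were not tested on such data. For the gene comparison edgeR recovered 20% of genes changed by a log2 fold of 1, 78% at 2, 94% at 3 and 94% at 4, with 7 false calls. For isoforms it recovered 0%, 24%, 38% and 46%, with 0 false calls, and 3 of 3 shifted lists were recovered with 0 false lists. Simulated genes varied independently, so the 0 false lists do not speak for lists whose genes vary together. For the same reason the recovered shares may not hold in the real comparison. In the real lists the estimated correlation ran from -0.03 for pro-apoptotic genes to 0.81 for mitochondrially encoded genes. Alternatives covered the pseudocount, the filter on low values, scaling, library weights, the variance model, the replicate number as a block, each library left out in turn, and the list test. limma on log2(FPKM + 1) became an alternative once counts were found. DESeq2, total-count scaling, omission of mitochondrial genes, 2 covariates and the permutation of list means were added after seeing the data. Fibroblast, blood cell and cumulus cell lists had 0, 3 and 4 genes above the filter, under the minimum of 5, and were not tested. None of these 7 genes passed.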

Results

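RNA was sequenced from pig morulae, embryos of the cleavage stage at which blastomeres compact before the blastocyst forms. Matured oocytes had been injected with a small interfering RNA (siRNA), activated without sperm and cultured to the morula. In 5 libraries the siRNA was directed against DDB1 (DDB1_KD), and in 5 it was a non-specific control siRNA (NC). Totals of 32466912 to 50911295 estimated counts per library covered 13522 to 14755 of the 24358 genes listed. The correlation of log2 expression between any 2 libraries was 0.946 at most, so no library was a copy of another. Nothing in the labels says whether the libraries of a group came from separate cultures, and p-values therefore measure the spread between these libraries, part of which can be technical. The series title names apoptosis and lineage differentiation as the processes under study, and the comparison of DDB1_KD with NC morulae addressed both.

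DDB1, the adaptor of the CUL4 ubiquitin ligases and a DNA damage sensor, was lower in DDB1_KD morulae. The gene (ENSSSCG00000013094) lies on chromosome 2 from 10171698 to 10200920 on the plus strand of the susScr11 build, with 1 listed isoform of 28 exons. Its level was 1.27 ± 0.227 FPKM (SD, n = 5) in DDB1_KD and 3.37 ± 0.708 FPKM (SD, n = 5) in NC. All 5 DDB1_KD libraries (142 to 262 counts) lay below all 5 NC libraries (304 to 753 counts). The fitted log2 fold change was -1.39 (SE 0.28), or 38.3% of NC in the fit, and an exact two-sided permutation test of its mean log2(FPKM + 1) over 252 assignments of the libraries gave p = 0.00794, the smallest it can give. DDB1 had the smallest p of all 8476 genes tested, but the adjusted p of edgeR's quasi-likelihood test was 0.977, and the adjusted p of DESeq2 was 0.0069.

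YAP1, the transcriptional coactivator at the end of the Hippo pathway that acts in trophectoderm specification, had the next smallest p. Its level was 0.672 ± 0.272 FPKM (SD, n = 5) in DDB1_KD and 2.79 ± 1.498 FPKM (SD, n = 5) in NC, a log2 fold change of -2.05 (SE 0.42). Counts were 66 to 219 in the DDB1_KD libraries and 319 to 1033 in the NC libraries, without overlap. YAP1 (ENSSSCG00000031429; chromosome 9, 32811231 to 32925606, plus strand) did not pass edgeR's test over all genes (adjusted p = 0.977). It passed DESeq2's test (adjusted p = 0.00715) and edgeR's test adjusted over the list alone, among 16 Hippo pathway genes (adjusted p = 0.00553). Of its 2 listed isoforms, ENSSSCT00000040218 had 0.488 ± 0.371 FPKM in DDB1_KD and 2.62 ± 1.54 FPKM in NC (SD, n = 5 each). The other isoform had 0.195 ± 0.274 and 0.196 ± 0.0984 FPKM.

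**Figure D1:**
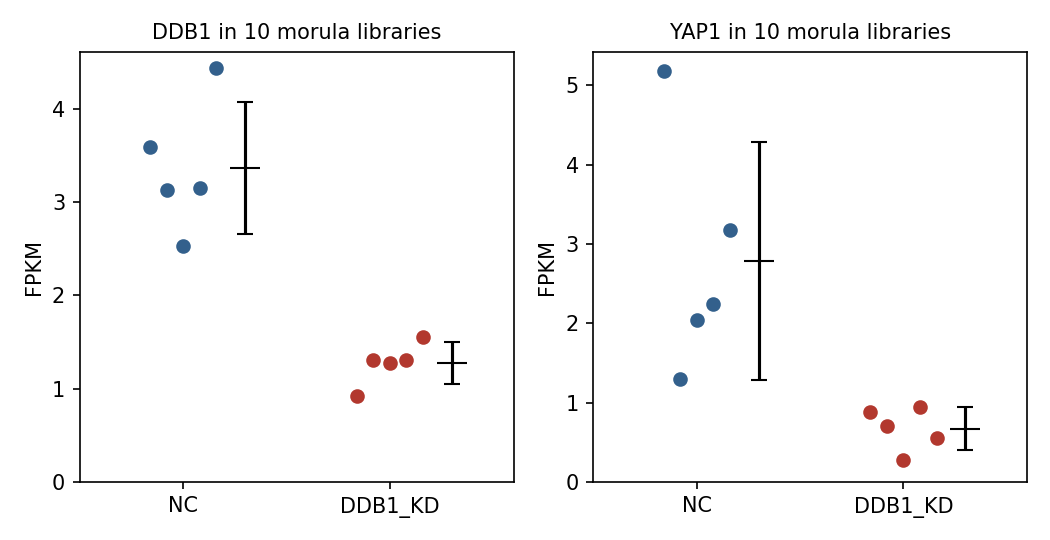
FPKM (vertical axes, from 0) of DDB1 on the left and YAP1 on the right, with 1 point per library and the mean ± SD of each group (n = 5) beside the points. The DDB1_KD libraries lie below the NC libraries for both genes, at means of 1.27 and 3.37 FPKM for DDB1 and of 0.672 and 2.79 FPKM for YAP1.

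No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. At an unadjusted p under 0.05 there were 245 genes, 149 higher and 96 lower in DDB1_KD, where chance alone would give 423.8. limma passed 0 genes (273 at an unadjusted p under 0.05), and DESeq2 passed 2, DDB1 and YAP1 (353 at an unadjusted p under 0.05). The 5 values of each group did not overlap for 29 genes (0.342%), and chance gives 0.794%, or 67.3 genes. The spread between libraries was wide, with a biological coefficient of variation of 47.6%. In data simulated from these libraries, 50 genes were changed at each log2 fold of 1, 2, 3 and 4, and genes varied independently. There edgeR recovered 20% of genes changed by a log2 fold of 1 and 78% of those changed by 2. The adjusted threshold loosens as more genes change strongly, so these rates may overstate recovery in the real comparison.

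The other genes with the smallest p did not pass. Lower in DDB1_KD by the fitted value were PMP22, a myelin membrane protein (log2 fold change -2.08, SE 0.56), AKR7A2, an aldehyde reductase (-1.34, SE 0.37), and PECAM1, an adhesion molecule (-1.09, SE 0.33). Higher were WASF1, a regulator of actin branching (1.42, SE 0.40), MLF1 (1.91, SE 0.55), ART3 (1.49, SE 0.43) and the zinc finger genes ZNF619 (1.39, SE 0.40) and ZNF568 (1.12, SE 0.33). Of these 8 genes, AKR7A2, WASF1 and ZNF568 had no overlap between the groups.

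Lineage markers were described by lists fixed beforehand. Of 15 trophectoderm markers tested, 13 had a lower value in DDB1_KD, with a median log2 fold change of -0.44. The list passed camera with a preset correlation (adjusted p = 0.000426) but not with an estimated correlation (adjusted p = 0.683). GATA3, a trophectoderm transcription factor, had 2.27 ± 2.13 FPKM in DDB1_KD and 5.86 ± 4.98 FPKM in NC (SD, n = 5 each; log2 fold change -1.34, SE 1.02). The endocytic adaptor DAB2 had a log2 fold change of -1.37 (SE 0.81), and the sodium pump subunit ATP1B1 one of -1.20 (SE 0.68). TEAD4, the DNA-binding partner of YAP1, stood at 0.07 (SE 0.34) and the ephrin EFNA1 at 0.74 (SE 0.47). Without NC replicate 5 GATA3 was at -0.77 and EFNA1 at 1.20, and without DDB1_KD replicate 4 ATP1B1 was at -1.86. TEAD4 ranged from -0.29 (without DDB1_KD replicate 4) to 0.26 (without NC replicate 5). CDX2 was below the filter, at a highest count of 16 in any library. DDB1_KD replicate 2 stood apart, with a list mean of 2.45 log2 CPM against 4.83 to 6.41 in the other 9 libraries. The mean log2 fold change of the list was -0.57, and -0.37 without that library or -0.86 without DDB1_KD replicate 4.

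Pluripotency and epiblast markers did not pass (adjusted p = 0.926), with 7 of 17 higher and 10 lower in DDB1_KD. Their median log2 fold change was -0.07 and camera's direction was down, whereas the mean was 0.09. That mean ranged from -0.013 to 0.20 when 1 library was left out. POU5F1, the core pluripotency factor, had 59.2 ± 36.9 FPKM in DDB1_KD and 81.0 ± 29.3 FPKM in NC (SD, n = 5 each). SOX2 had a log2 fold change of 0.43 (SE 0.52), NANOG 0.54 (SE 0.79), DPPA2 0.52 (SE 0.24) and TBX3 -0.43 (SE 0.31). Primitive endoderm markers had 6 of 7 lower values (median -0.32, adjusted p = 0.157), and passed camera without DDB1_KD replicate 5 (adjusted p = 0.0314). With an estimated correlation and all libraries the adjusted p was 0.683, and the mean log2 fold change, -1.04, was -0.12 without NC replicate 5. GATA6, a primitive endoderm regulator, had a log2 fold change of -0.32 (SE 0.27). The apolipoprotein APOA1 had a log2 fold change of -5.23 (SE 2.08), which rested on NC replicate 5 at 10.0 FPKM and was 1.35 (SE 1.36) without that library. No count was listed for SOX17 in any library, which allows up to 3 counts in each. When 1 library was left out, POU5F1 ranged from -0.81 (without DDB1_KD replicate 4) to -0.26 (without NC replicate 1) and SOX2 from 0.092 (without DDB1_KD replicate 4) to 0.73 (without NC replicate 5). NANOG ranged from -0.28 (without DDB1_KD replicate 2) to 1.31 (without NC replicate 4), and GATA6 from -0.53 (without DDB1_KD replicate 4) to -0.14 (without DDB1_KD replicate 2), where TBX3 was at -0.24.

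Genes of apoptosis were split. Of 16 pro-apoptotic genes, 8 were higher and 8 lower in DDB1_KD (median log2 fold change -0.02, mean 0.05, camera's direction up, adjusted p = 0.823). Their mean ranged from -0.11 to 0.11 when 1 library was left out. PMAIP1, a BH3-only activator of apoptosis, had 19.6 ± 13.99 FPKM in DDB1_KD and 10.1 ± 4.18 FPKM in NC (SD, n = 5 each; log2 fold change 1.02, SE 0.45, and 0.48, SE 0.35, without DDB1_KD replicate 3). CASP6, an effector caspase gene, had a log2 fold change of 0.48 (SE 0.27), and of 0.26 without DDB1_KD replicate 3. BAX was below the filter, at no more than 0.567 FPKM in any library. Of 12 anti-apoptotic genes, 9 had a lower value in DDB1_KD (median -0.20, adjusted p = 0.194), among them BCL2L1 (-0.72, SE 0.47) and survivin, BIRC5 (-0.35, SE 0.17). BCL2L1 ranged from -1.10 (without DDB1_KD replicate 5) to -0.46 (without DDB1_KD replicate 4).

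CDKN1A, the p21 inhibitor of cyclin-dependent kinases, had 9.57 ± 6.40 FPKM in DDB1_KD and 12.2 ± 8.87 FPKM in NC (SD, n = 5 each). MDM2, a ubiquitin ligase gene, had a log2 fold change of -0.14 (SE 0.34). When 1 library was left out, CDKN1A ranged from -0.78 (without DDB1_KD replicate 3) to 0.12 (without NC replicate 3) and MDM2 from -0.30 (without NC replicate 4) to 0.067 (without DDB1_KD replicate 2). The 37 DNA damage response and repair genes had a median of 0.00 (19 higher, 18 lower, adjusted p = 0.823). FANCD2, of the Fanconi anaemia pathway, had 3.54 ± 0.560 FPKM in DDB1_KD and 2.49 ± 0.320 FPKM in NC (SD, n = 5 each), without overlap. XRCC6, the Ku70 subunit of end joining, had a log2 fold change of 0.59 (SE 0.25). Neither gene passed over all genes.

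The CUL4 ligase genes other than DDB1 had 12 higher and 11 lower values among 23 tested (adjusted p = 0.926). DCAF13, a substrate receptor, had 227 ± 128 FPKM in DDB1_KD and 135 ± 28.7 FPKM in NC (SD, n = 5 each; log2 fold change 0.76, SE 0.37, and 0.50, SE 0.35, without DDB1_KD replicate 2), and CUL4B a log2 fold change of -0.42 (SE 0.30). Genes of 10 known CUL4 ligase substrates were split 5 to 5 (adjusted p = 0.856), with CDT1, the replication licensing factor, at -0.45 (SE 0.41) and CHEK1 at 0.20 (SE 0.24). CDT1 ranged from -0.78 (without DDB1_KD replicate 4) to -0.25 (without DDB1_KD replicate 2) and CHEK1 from 0.060 (without NC replicate 5) to 0.32 (without NC replicate 1), and CUL4B was at -0.23 without DDB1_KD replicate 1. These values are of RNA, and protein was not measured here.

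Maternal oocyte transcripts, which are cleared as the embryo activates its own genome, had the smallest list p by camera with a preset correlation. Of 21 tested, 20 had a higher value in DDB1_KD, with a median log2 fold change of 0.84 (camera adjusted p = 5.68e-06 with a preset correlation, 0.683 with an estimated correlation). The zona pellucida gene ZP4 had 10.8 ± 11.1 FPKM in DDB1_KD and 2.67 ± 1.47 FPKM in NC (SD, n = 5 each; log2 fold change 2.02, SE 0.66, and 1.30, SE 0.58, without DDB1_KD replicate 2). ZP2 had a log2 fold change of 1.06 (SE 0.54) and CNOT7, a deadenylase subunit, one of 0.60 (SE 0.29). The list mean was 3.67 ± 1.31 log2 CPM in DDB1_KD and 3.07 ± 0.748 in NC (SD, n = 5 each; exact two-sided permutation p = 0.381, adjusted 0.841). The DDB1_KD libraries ranged from 1.69 in replicate 1 to 4.91 in replicate 2, beyond the NC range of 2.23 to 4.11 on both sides. Without DDB1_KD replicate 2 the mean log2 fold change of the list was 0.48, against 0.87 with all libraries.

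Mitotic genes went with the maternal list in direction. Of 29 G2 and M phase genes, 22 had a higher value in DDB1_KD (median log2 fold change 0.16, camera adjusted p = 0.00602, and 0.683 with an estimated correlation). CDK1, the mitotic kinase, had 77.6 ± 36.9 FPKM in DDB1_KD and 45.5 ± 12.6 FPKM in NC (SD, n = 5 each), and the checkpoint gene MAD2L1 a log2 fold change of 0.70 (SE 0.31). This call was lost without DDB1_KD replicate 2 (adjusted p = 0.0536), DDB1_KD replicate 5 (0.0969) or NC replicate 1 (0.0884). With the maternal transcript level as a covariate, an alternative added after seeing the data, it was lost too (adjusted p = 0.0925), and the mean log2 fold change was 0.11 against 0.20.

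Genes of the unfolded protein and integrated stress responses had 19 of 22 lower values in DDB1_KD (median log2 fold change -0.36, camera adjusted p = 0.00403, and 0.683 with an estimated correlation). CANX, an endoplasmic reticulum chaperone, had 22.1 ± 7.72 FPKM in DDB1_KD and 39.8 ± 8.47 FPKM in NC (SD, n = 5 each; log2 fold change -0.86, SE 0.27), and the one-carbon enzyme gene SHMT2 a log2 fold change of -0.70 (SE 0.33). Without NC replicate 1 the call was lost (adjusted p = 0.0884). The mean log2 fold change of the list, -0.29, was -0.18 without that library, -0.19 without NC replicate 2 and -0.54 without DDB1_KD replicate 4.

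Cytosolic ribosomal protein genes had 62 of 66 lower values (median log2 fold change -0.17, camera adjusted p = 2.8e-05, and 0.683 with an estimated correlation). RPL23 had 1227 ± 224 FPKM in DDB1_KD and 1502 ± 191 FPKM in NC (SD, n = 5 each). Pseudogene copies can share reads with these genes, so their single values are uncertain. Without DDB1_KD replicate 2 the call was lost (adjusted p = 0.0572). The mean log2 fold change of these genes, -0.16, was -0.07 without that library and -0.10 without NC replicate 1. All 13 mitochondrially encoded genes had higher values (median 0.35, camera adjusted p = 0.0041, and 0.683 with an estimated correlation), as COX1, a subunit of cytochrome c oxidase, at 0.47 (SE 0.25) and at 0.18 without DDB1_KD replicate 5. The share of counts from the mitochondrial chromosome was 12.2% to 24.4% in DDB1_KD and 8.58% to 18.4% in NC. This call was lost without DDB1_KD replicate 5 (adjusted p = 0.48), NC replicate 1 (0.213) or NC replicate 3 (0.055), and with limma after quantile normalisation (0.0818). The mean log2 fold change, 0.34, was 0.07 without DDB1_KD replicate 5, 0.21 without NC replicate 1 and 0.55 without NC replicate 4.

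Cell junction and polarity genes had 17 of 24 lower values (adjusted p = 0.101; 0.0348 with no filter and 0.0498 with limma after quantile normalisation). With an estimated correlation the adjusted p was 0.683, and the mean log2 fold change, -0.14, ranged from -0.23 (without DDB1_KD replicate 4) to -0.069 (without DDB1_KD replicate 2). Among them were the desmosomal gene DSP at -0.57 (SE 0.24) and EZR, of the apical cortex, at -0.56 (SE 0.29), or -0.37 without DDB1_KD replicate 2. The 16 Hippo pathway genes and YAP targets had 9 higher and 7 lower values and did not pass (adjusted p = 0.164). Their median was 0.04, whereas the mean, -0.21, and camera's direction were down. Among them TEAD1 had a log2 fold change of -0.58 (SE 0.30) and VGLL4, a repressor of YAP1 activity, one of -0.93 (SE 0.51). Over the 27 lists tested, no member passed edgeR's test over all genes, and YAP1 alone passed it adjusted over the list alone. YAP1 also passed DESeq2 over all genes, but in 71 of 99 other splits of the libraries some gene had an adjusted p as small. None of the 6 list calls held with an estimated correlation, by fry or by exact permutation of the list means.

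**Figure D2:**
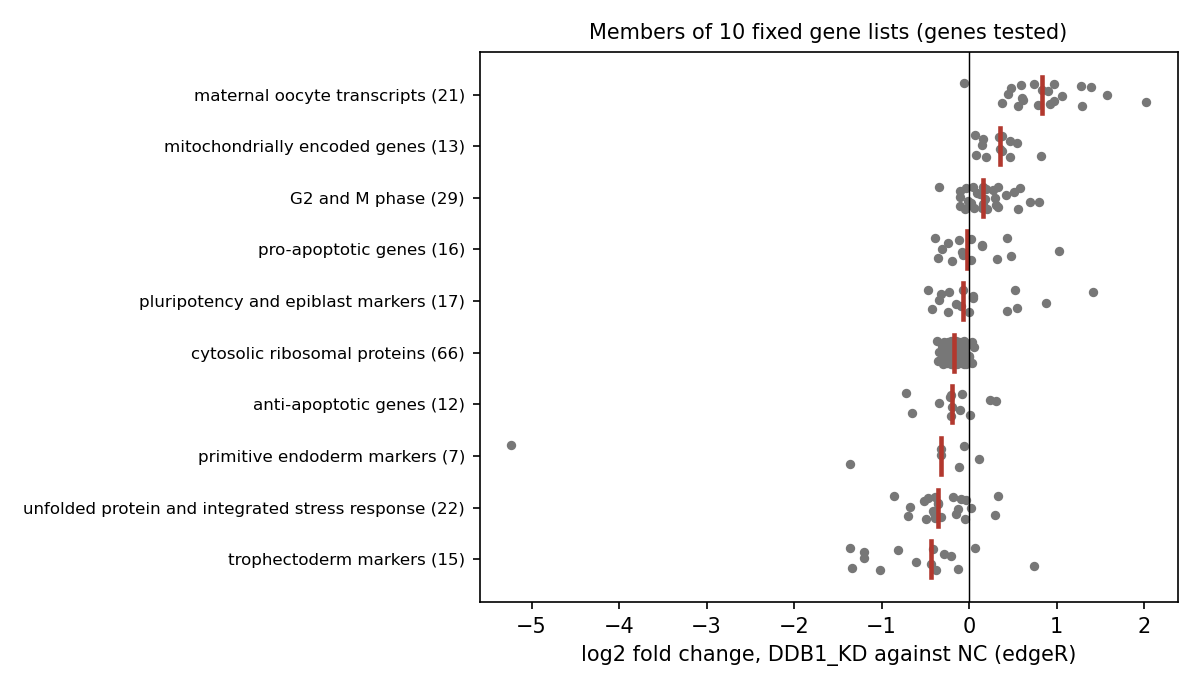
Fitted log2 fold change (horizontal axis, DDB1_KD against NC) of each member of 10 fixed gene lists, with 1 grey point per gene, a red bar at the list's median and the number of genes tested after each name. Medians run from -0.44 for trophectoderm markers to 0.84 for maternal oocyte transcripts, and the point at -5.23 is APOA1.

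The largest differences between libraries did not separate the groups. The first principal component of log2 CPM held 32.04% of the variance and the second 13.5%, and on both the groups overlapped. On the first, DDB1_KD replicates 2, 3 and 5 scored 72.9, 37.2 and 42.9, above all NC libraries (highest 13.2). DDB1_KD replicates 1 and 4 scored -31.0 and -47.6. All 21 maternal transcripts correlated positively with the first component (median r = 0.759 across libraries), as did 13 of 13 mitochondrially encoded genes (median r = 0.539), while 13 of 15 trophectoderm markers correlated negatively (median r = -0.593). With that component as a covariate, an alternative chosen after seeing the data, no list passed (smallest adjusted p = 0.233). The component was computed from the same values and tracks the maternal list, so this loss was partly built in. The mean correlation between libraries was 0.887 within DDB1_KD and 0.925 within NC, a difference with an exact two-sided permutation p of 0.0635 over 252 assignments.

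**Figure D3:**
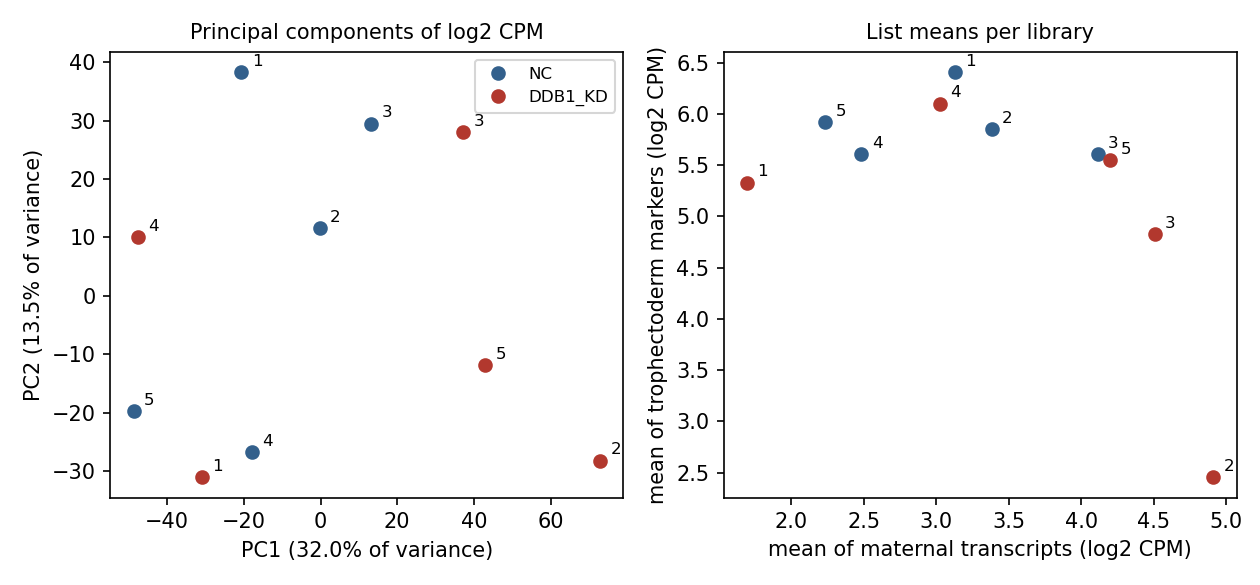
Left, the first and second principal components of log2 CPM, and right, the mean log2 CPM of maternal oocyte transcripts (horizontal) and trophectoderm markers (vertical), with 1 numbered point per library. DDB1_KD replicate 2 has the highest maternal mean, 4.91, and the lowest trophectoderm mean, 2.45.

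Among 11250 isoforms tested, 1 passed edgeR's test, an isoform of RARS2, the mitochondrial arginyl-tRNA synthetase (ENSSSCT00000004760, 22 exons; adjusted p = 0.0412). At an unadjusted p under 0.05 there were 378 isoforms, limma passed 1 isoform, and DESeq2 passed 68. The RARS2 isoform had 4.76 ± 1.40 FPKM (SD, n = 5) in NC and a count of 0 in each DDB1_KD library, which allows up to 3 counts or 0.0426 FPKM per library. The RARS2 isoform ENSSSCT00000041379, of 21 exons, showed the opposite pattern, with 7.88 ± 4.595 FPKM (SD, n = 5) in DDB1_KD and a count of 0 in each NC library (up to 0.0399 FPKM), and did not pass edgeR's test (adjusted p = 0.189). It passed DESeq2 (adjusted p = 1.13e-19), and limma with a pseudocount of 0.1 or with library weights passed 2 RARS2 isoforms. DESeq2's 68 calls included fitted log2 fold changes as extreme as -29.5 for ACTB and 28.6 for HSPA8 (SE 3.03 each). In edgeR the same ACTB isoform had an unadjusted p of 0.0114 and an adjusted p of 0.9997. No splits of the libraries were run with DESeq2 on isoforms either, so DESeq2's isoform calls are weak evidence. The remaining RARS2 isoform was listed in every library. The RARS2 gene (chromosome 1, 55893480 to 55982068, minus strand) had a log2 fold change of 0.58 (SE 0.41). Isoforms of 1 gene share most of their reads, so these values depend on how reads were assigned to isoforms. When 1 library was left out, an isoform of RARS2 passed in 1 of 10 fits, the one without DDB1_KD replicate 4.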

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

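In each group of 5 libraries, the library farthest from the rest was compared with the others by Dixon's ratio of its gap to the whole range. Of 242 groups of values compared, 9 exceeded the critical value of 0.71, and chance alone gives about 12.1. All values are log2 CPM, and no test of their causes was run.

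DDB1_KD replicate 2 was low for the mean of primitive endoderm markers, at 2.89 against 4.47 to 5.04 in the other DDB1_KD libraries. The same library was low for DAB2 (1.71 against 8.07 to 9.30), MDM2 (5.12 against 6.66 to 6.90) and VGLL4 (-0.54 against 2.2 to 3.13). DAB2 is 1 of the 7 tested primitive endoderm markers, so its flag and that of the list are not independent. DDB1_KD replicate 5 was low for EFNA1, at 3.57 against 5.45 to 6.01, and high for COX1, at 15.57 against 14.34 to 14.67. NC replicate 5 was high for APOA1, at 4.94 against -4.37 to -1.69 in the other NC libraries. NC replicate 3 was low for MTHFD2, at 5.81 against 6.89 to 7.18, and NC replicate 1 was low for NBR1, an autophagy receptor gene, at 4.42 against 4.91 to 5.04.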

How the results depend on the processing

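The alternatives with DESeq2, total counts, no mitochondrial genes, the 2 covariates and the exact permutation were chosen after seeing the data, and limma on log2(FPKM + 1), the test written first, became an alternative once the tables proved to hold counts. The DDB1 log2 fold change was negative under every alternative, and -1.49 to -1.28 when 1 library was left out. It did not pass edgeR or limma under any of them, and with DESeq2 it was -1.36 and passed (adjusted p = 0.0069), where the range over the other alternatives was 0.469 to 0.9999. The number of genes passed was 0 in every alternative run except DESeq2, which passed 2. The number of isoforms passed was 2 with limma at a pseudocount of 0.1 or with library weights, 0 with no filter, with a filter of 10 FPKM and with a robust fit, 68 with DESeq2, and 0 to 2 when 1 library was left out, against 1 reported. The number of lists passed was 6 as reported, and 0 with an estimated correlation, with fry, with exact permutation of the list means or with the first principal component as a covariate. With the maternal transcript level as a covariate it was 4, with the maternal list itself not counted. It ranged from 3 (without NC replicate 1) to 7 when 1 library was left out. The cause of these changes was not tested, and the fits that leave out 1 library also have fewer samples.

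With the replicate number as a block, 0 isoforms passed, and no other count of calls moved by over 1.5 times. The numbers did not pair the libraries: same-numbered libraries had correlations of -0.0563, 0.129, 0.354, -0.0527 and -0.142 between their deviations from the group means, and only the libraries numbered 3 correlated best with each other.

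Sign changes were counted where the reported value exceeded its SE. APOA1 was 0.95 with the replicate number as a block and ranged from -5.73 to 1.35 when 1 library was left out. With the maternal transcript level as a covariate RRM2B was -0.32 and PAX6 -0.58. With the first principal component as a covariate RRM2B was -0.35, PAX6 -0.68, DPPA5 -0.11 and ATP8 -0.043. The autophagy list mean was -0.22 with no filter and -0.0022 with library weights. The cause was not tested.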

Other observations

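The tests chosen only after the result was seen were YAP1 without each library, the correlations with trophectoderm markers and with depth, the permutation of maternal transcripts, the count of isoforms listed in 1 group only, the splits for genes, the DESeq2 splits and the principal component covariate. The maternal covariate was added after seeing the data, but its test on YAP1 was set before that result was seen. The 4 lists described next were also picked after their values were seen.

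Autophagy genes had 13 higher and 11 lower values in DDB1_KD (camera adjusted p = 0.394). NBR1, an autophagy receptor, had 5.77 ± 0.721 FPKM in DDB1_KD and 3.81 ± 0.616 FPKM in NC (SD, n = 5 each), without overlap, and the initiating kinase ULK1 a log2 fold change of 1.28 (SE 0.45). SQSTM1, the receptor p62, stood at -0.66 (SE 0.34), and at -1.02 without DDB1_KD replicate 4. Histone modifiers had 13 higher and 12 lower values (adjusted p = 0.845), with the deacetylase HDAC1 at -0.82 (SE 0.34) and the methyltransferase EZH1 at 1.31 (SE 0.59). Glycolysis genes had 7 higher and 9 lower values (median -0.07, mean 0.00, camera's direction down, adjusted p = 0.856), with ENO1 at -0.73 (SE 0.26) and PGK1 at 0.41 (SE 0.20). Antioxidant genes had 12 higher and 9 lower values but camera's direction was down (mean log2 fold change -0.07, adjusted p = 0.561). Their mean ranged from -0.16 to 0.031 when 1 library was left out. They passed with a filter of 10 FPKM, also in the lower direction (mean -0.24, adjusted p = 0.0392). With an estimated correlation and the filter of 1 FPKM the adjusted p was 0.875. Thioredoxin reductase, TXNRD1, stood at -0.56 (SE 0.21) and glutaredoxin, GLRX, at -1.33 (SE 0.71), or -0.84 without NC replicate 1. None of these genes passed over all genes.

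The other lists reported here did not pass camera. Nuclear-encoded oxidative phosphorylation genes had 27 of 38 lower values (adjusted p = 0.192), and passed without DDB1_KD replicate 3 (0.0103) or NC replicate 5 (0.0152). With an estimated correlation and all libraries their adjusted p was 0.875. DNA replication genes had 16 of 30 lower values (adjusted p = 0.823), genes of embryonic genome activation 9 of 15 (0.823; median -0.03, but mean 0.04 and camera's direction up), and genes of DNA methylation 7 of 13 (0.448). Ubiquitin and proteasome genes had 18 of 30 higher values (0.561) and ribosome biogenesis genes 18 of 31 (0.856; median 0.04, camera's direction up, mean -0.00). Genes of FGF, MAPK and WNT signalling were split 6 to 6 (0.194).

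YAP1 was lower in all 5 DDB1_KD libraries than in any NC library. With the maternal transcript level as a covariate the log2 fold change was -1.91 (SE 0.41). Delay of the embryos, as measured by that level, was thus argued against as the whole cause. The maternal mean was 3.67 ± 1.31 log2 CPM in DDB1_KD and 3.07 ± 0.748 in NC (SD, n = 5 each). A mean that separates the groups so little could remove little of the difference. Delay not seen in maternal transcripts therefore stays open. A single library was also argued against, since the YAP1 log2 fold change stayed at -1.69 or below without any 1 of the 10. YAP1 was picked for its small p, which favours genes that do not rest on 1 library, so this check is weak. Chance stays open: in 66 of 99 other splits of the libraries some gene had a p as small in edgeR, and in 71 of 99 an adjusted p as small in DESeq2. An effect of the DDB1 siRNA, the difference the labels name between the groups, stays open and was not tested apart from chance.

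Maternal transcripts were higher and trophectoderm markers lower in DDB1_KD by the fitted values. Chance spread in developmental progress between libraries could account for the maternal list, whose exact two-sided permutation p was 0.381, and for trophectoderm markers it was 0.0873 (adjusted 0.643), short of the threshold. Whether both lists follow 1 axis cannot be told apart from separate variation at 10 libraries: r was -0.575 (permutation p = 0.0626, adjusted 0.188 over 3 relations; rho -0.515, permutation p = 0.135; 95% interval -0.884 to 0.0857), and -0.615 without the 2 libraries farthest out. Depth also stays open, with r = -0.211 between the maternal mean and total counts (permutation p = 0.55; rho -0.285, permutation p = 0.427; 95% interval -0.742 to 0.483; -0.256 without 2 libraries). An effect of the DDB1 siRNA on progress stays open too.

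An isoform of RARS2 was listed in NC libraries alone and another in DDB1_KD libraries alone. Among all isoforms, 12 were counted in every library of 1 group and in none of the other. Chance could not be excluded for that number, because 58 of the 126 splits of the libraries gave as many, and the highest of the others gave 24. The number took any count above 0, such as an NPY isoform at 1 to 9 counts. It did not look for 2 isoforms of 1 gene in opposite groups. The RARS2 isoforms had 316 to 498 and 123 to 1292 counts, and chance was not tested for RARS2 alone. No biological explanation was tested for this pattern.

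The real split gave 0 genes, a count that 100 of 100 splits must reach, so that count says nothing about chance. At an unadjusted p under 0.05 the real split gave 245 genes, the median split 278, and 61 of 100 splits gave at least as many, so chance was not excluded. At an adjusted p under 0.05 the highest of the other splits gave 83 genes. The same split had the most genes at an unadjusted p under 0.05, 2126. On 1 side it held DDB1_KD replicates 1 and 4 and NC replicates 1, 4 and 5. These libraries had the lowest scores on the first principal component, -48.7 to -18.0, and NC replicate 2 was next at -0.257. For isoforms 13 of 30 splits gave at least the real count of 1 (highest other 2), and for lists 26 of 100 gave at least the real count of 6 (highest other 10), so chance was not excluded for either. With DESeq2, 68 splits gave at least 2 genes, and the highest of the others gave 1043. The correlation of maternal transcripts with the mitochondrial share was r = 0.357 (permutation p = 0.32, adjusted 0.48; rho 0.297, permutation p = 0.407), and 0.267 without 2 libraries.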
